A study of Arabidopsis thaliana with 12 samples.

How the data were processed

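RNA of wild-type Arabidopsis thaliana, ecotype Landsberg, was measured on 12 single-channel expression arrays. Per the labels, 6 arrays came from plants kept for 48 h in white light at 20 µE and 6 from plants kept for 48 h in blue light at 200 µE. The colour and the strength of the light changed together, so their effects cannot be separated here. The arrays of each group were numbered 1 to 6 in the labels, which do not say whether they came from separate plants, so p-values measure only the spread between these arrays, which may be technical.

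The deposited values were intensities on a linear scale, 1 per probe and array, for 3439 probes. No column exceeded 100, and every column held exact zeros, from 404 to 628 per array. A single probe stood at 100, within 0.001, on all blue arrays. The scanner, the background step, the scaling to 100 and any averaging of spots by the authors are not given in the sources used here. Total intensity per array ran from 1044 to 3337, so the columns were taken as not normalised between arrays. The table held 0 columns of other series.

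A value of 0 was treated as missing, the rest were log2 transformed and the 12 arrays were quantile normalised. Probes with at least 3 values above 0 in each group were tested, which kept 2840 and left out 599. Each probe was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05 on the adjusted p. Fold changes are blue over white, and intervals are 95% intervals of that fit. Normalised intensities are given as mean ± SD. The number of arrays limits the precision of each value. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

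Before the data were examined, a rule was set for arrays that could be repeat measurements of 1 sample. Pairs were to be averaged if, in the deviations from the group means, the arrays of both groups formed mutual best pairs with the same numbers, each with a correlation over 0.3. All 6 adjacent pairs were mutual best partners, but blue arrays 3 and 4 correlated at only 0.141, so the 12 arrays entered as separate samples. Adjacent arrays were close in total intensity in every pair, with 3316 and 3337 on blue arrays 3 and 4. That pair also had similar numbers of zeros (618 and 628), so repeat measurements stay open for it too. The fit with adjacent arrays averaged, 3 against 3, is printed beside the results, because p-values over 12 arrays may be too small and intervals too narrow. The shared numbers also paired white with blue arrays. The 6 correlations of deviations between arrays of the same number lay between 0.136 and 0.293, and all 12 arrays correlated best with their own number in the other group. That pairing comes from the values, since the labels give only the numbers.

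On simulated values for this comparison (2840 probes, 200 of them changed), arrays without shared deviations gave 77% of probes with a log2 change of 2 recovered by the fit on 12 arrays, with 4.94% of calls false. When adjacent arrays shared their deviations, 30.3% of the calls of that fit were false at a log2 change of 2 and 46.6% at a log2 change of 1. The averaged fit, which tested 2669 probes with 192 of them changed, then recovered 62.5% of probes with a log2 change of 2, with 2.44% of calls false, and 0% of 189 with a log2 change of 1. In the data 45.1% of the tested probes were called over 12 arrays, a far larger share than was changed in the simulation. Shares of false and recovered calls depend on that share, so the simulated ones do not carry over to the data. The simulation also left out the similarity of white and blue arrays with the same number, which correlated at 0.136 to 0.293 in the data.

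Probe names came from the array annotation, which can be old, updated through a RefSeq gene table of assembly TAIR10.1. Of the probes, 692 had 1 gene, 870 had several and 1877 were unnamed here. Among those with 1 gene, 690 matched the table. Only probes with 1 gene are named, and no coordinates are given because the build behind the probes is not given in the sources used here. The genes named are the 8 largest rises and 8 largest falls past the threshold and, in each gene list with at least 3 tested members, the 2 with the smallest p. Genes outside this rule are marked as chosen after their values were seen.

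The 21 gene lists fixed before the data were examined held 329 genes, of which 13 were tested. A further 6 lists were written after the annotation was read and before any fold change was joined to a gene. Lists with 3 or more members among the 2378 probes without a 0 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation.

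The alternatives were the deposited scale, median centring, a pseudocount of 0.0248 (the 5th percentile of values above 0), filters that left out the dimmest 25% or 50% of probes, a trended and robust variance, the replicate number as a block, averaging of arrays 1 number or 3 numbers apart, leaving out each array and each number, and a fold change of at least 2. Alternatives added after the data were seen averaged adjacent arrays with a block, left out white arrays 5 and 6 or these numbers in both groups, removed the similarity of probes 6 numbers apart, and joined the pseudocount to an estimated correlation for the fixed lists. Other splits of the arrays were refitted, with 100 splits where there were more.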

Results

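Gene expression of wild-type Landsberg plants was compared between 48 h of blue light at 200 µE and 48 h of white light at 20 µE, with 6 arrays per regime. Total intensity averaged 1983 ± 832 (SD, n = 6) on the white arrays and 3078 ± 228 (SD, n = 6) on the blue arrays. White arrays 5 and 6 were lowest, with totals of 1044 each. Values of 0 numbered 488 ± 65 (SD, n = 6) on white and 594 ± 24 (SD, n = 6) on blue arrays.

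The comparison asked which transcripts differed between strong blue and weak white light. Blue light went with a 24.8-fold rise (95% interval 15.3 to 40.3) of AT1G78620, the phytyl phosphate kinase VTE6 of tocopherol synthesis, and with a 3.15-fold rise (2.34 to 4.24) of PSBW, a small subunit of photosystem II. NTRC, a plastid thioredoxin reductase, rose 3.74-fold. LHB1B2, a light-harvesting chlorophyll-binding protein of photosystem II, fell by 1.68 on the log2 scale, and GLDH, the last enzyme of ascorbate synthesis, fell by 2.28. Each of these 5 genes passed the threshold both over 12 arrays and with adjacent arrays averaged, and LHB1B2 did not pass on the deposited scale.

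Over 12 arrays, 1280 of 2840 probes changed, 551 of them higher and 729 lower under blue light. With adjacent arrays averaged, 527 of 2669 probes changed, 226 higher and 301 lower, and 524 of them had changed in the same direction over 12 arrays. On the deposited scale the split turned, with 869 higher and 331 lower, and the median log2 fold change of all tested probes moved from -0.10 to 0.44. Directions are therefore relative to the typical probe. Among the 563 tested probes with 1 gene, 106 were higher and 152 lower over 12 arrays, and 43 and 61 of these also changed with pairs averaged.

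**Figure D1:**
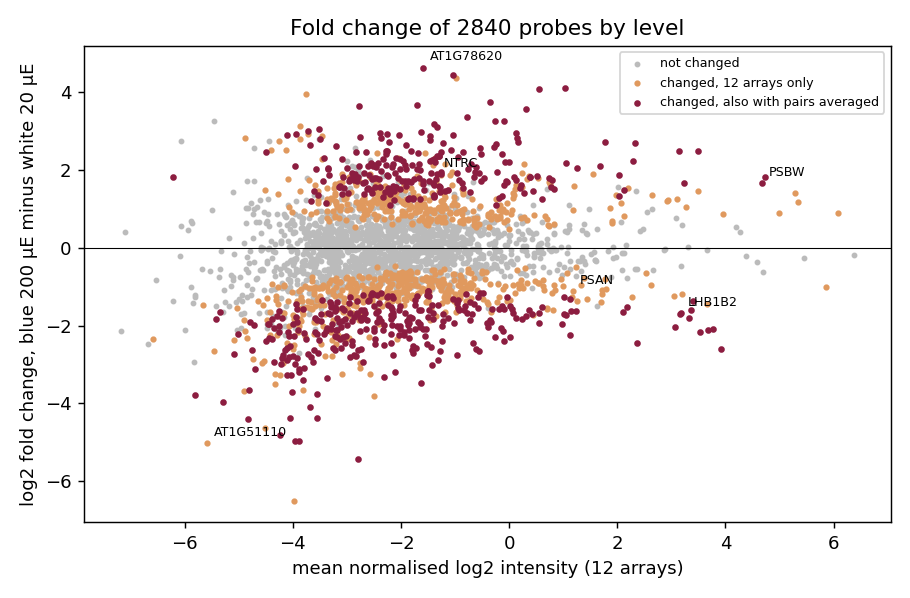
Each point is 1 of 2840 probes, with the mean normalised log2 intensity of the 12 arrays on the x axis and the log2 fold change, blue over white, on the y axis. Probes that changed over 12 arrays are orange, those that also changed with pairs averaged are dark red, and probes that did not pass are grey; points above and below 0 are seen across the range of levels.

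Among the largest rises, AT1G78620 went from a normalised intensity of 0.0634 ± 0.0261 (n = 5) to 1.43 ± 0.121 (n = 6), a log2 fold change of 4.63 ± 0.32 (SE, limma adjusted p = 2.56e-06, and 0.00285 with pairs averaged). AT2G31800 rose 8.63-fold (adjusted p = 5.80e-05, and 0.0109 averaged) and AT1G16080 7.69-fold (2.54e-05 and 0.00869). OSB1, a mitochondrial protein that binds single-stranded DNA, rose 8.29-fold (6.06e-05 and 0.00489). AT4G31210, a DNA topoisomerase, had a log2 fold change of 2.94 ± 1.01 (adjusted p = 0.0337, and 0.0482 averaged), but an adjusted p of 0.114 with the replicate number as a block. Its call also ended in 7 of 12 refits without 1 array (white 1, 3 or 6, or blue 1, 2, 3 or 4), and its log2 fold change ran from 2.04 without white array 3 to 4.25 without white array 5. With pairs averaged and a block its adjusted p was 0.0534. AT3G60590, AT3G58570 and AT4G20760 passed over 12 arrays at log2 fold changes of 2.83, 2.80 and 2.74, but had adjusted p-values of 0.0511, 0.151 and 0.0588 with pairs averaged. When the averaged pairs also had a block, AT3G60590 passed (0.0197) and the other 2 did not (0.0609 and 0.0512). AT3G60590 was at 2.05 without white array 5. AT4G20760 was at 3.36 without number 5, 3.44 without white arrays 5 and 6 and 3.80 without these numbers in both groups. Its log2 fold changes were 2.93 for arrays 1 and 2, 4.85 for arrays 3 and 4 but 0.44 for arrays 5 and 6. With the pseudocount AT3G60590, AT3G58570 and AT4G20760 were smaller, at 1.81, 1.68 and 1.96, and each still passed. The call of AT3G58570 ended in 5 of 12 refits without 1 array (white 5, or blue 1, 2, 3 or 4), on the deposited scale (adjusted p = 0.0610) and with median centring (0.0583), and its log2 fold change was 1.94 without white array 6. Its fold change was 3.25 times smaller without white arrays 5 and 6, and the log2 fold change was 5.61 for that pair of numbers but 1.78 for arrays 1 and 2 and 1.0 for arrays 3 and 4.

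Among the largest falls, AT1G70350 fell by 4.36 ± 0.48 (SE) on the log2 scale (adjusted p = 2.24e-05, and 0.00489 averaged), lower in 6 of 6 number-matched comparisons. AT1G10310, a pterin aldehyde reductase, fell by 3.02 ± 0.26 (4.16e-06 and 0.00489). AT1G07850 fell by 4.40 (0.00132 and 0.00489) and AT4G18540 fell by 3.19 (0.00284 and 0.0160). With the pseudocount AT4G18540 was at -1.38 and did not pass (adjusted p = 0.0799). AT1G79220, a protein of the mitochondrial transcription termination factor family, fell by 3.28 (0.00377 and 0.0339) with 4 blue arrays above 0. These falls were smaller without 1 blue array, with log2 fold changes of -3.65 for AT1G07850 and -2.51 for AT4G18540 without blue array 2 and -2.36 for AT1G79220 without blue array 3, and each still passed. AT1G07850 was at -5.08 without number 5, and AT4G18540 at -3.85 without numbers 5 and 6 of both groups. AT1G51110, a fibrillin, AT1G13970 and SRX, the sulfiredoxin that restores oxidised peroxiredoxins, had log2 fold changes of -5.02, -3.25 and -2.97 over 12 arrays. These 3 probes had 3, 4 and 3 blue arrays above 0 and could not be tested with pairs averaged, and AT1G51110 had an adjusted p of 0.0693 with the replicate number as a block. AT1G51110 was higher in 1 of 3 number-matched comparisons, with log2 fold changes of -7.88 for arrays 1 and 2 and -0.24 for arrays 5 and 6. With the pseudocount it was at -1.49. Mean normalised blue intensities were 0.0110 for AT1G51110, 0.0139 for AT1G07850, 0.0182 for SRX, 0.0214 for AT1G79220 and 0.0242 for AT1G70350. These lie below the pseudocount of 0.0248, so the sizes of these falls depend on how values near 0 are handled.

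**Figure D2:**
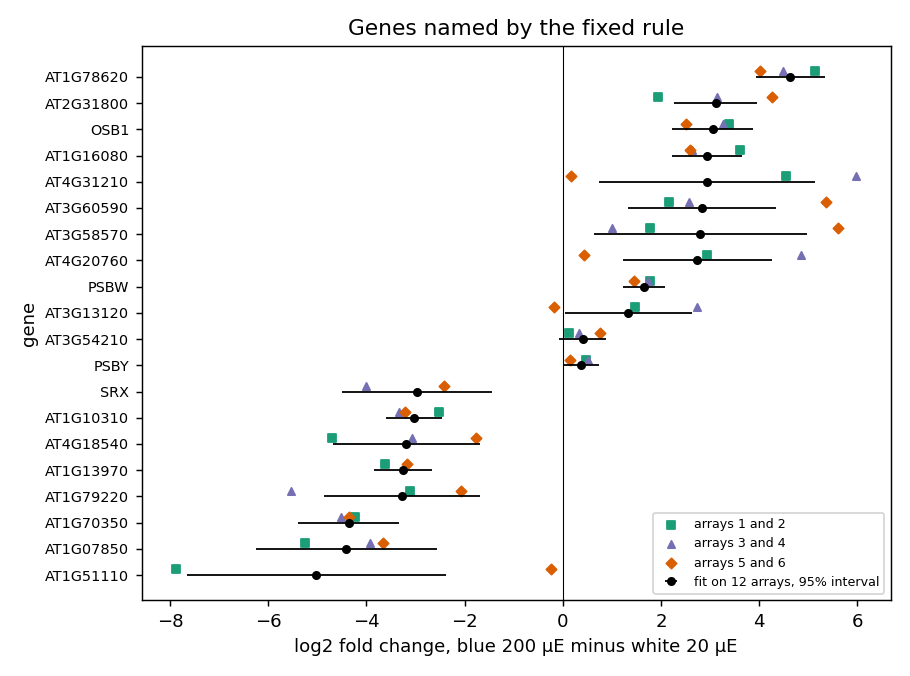
Black points are log2 fold changes, blue over white, of the genes named by the rule, with bars for the 95% interval over 12 arrays, and coloured symbols are the fold changes of each pair of adjacent arrays. The 3 pairs lie close together for AT1G70350 and apart for AT4G31210.

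Genes of the photosynthetic apparatus moved in both directions. In the photosystem II list, PSBW rose from a normalised intensity of 14.5 ± 2.01 to 46.0 ± 8.64 (n = 6 each, log2 fold change 1.66 ± 0.20 SE, limma adjusted p = 4.32e-05, and 0.0164 with pairs averaged), higher in 6 of 6 number-matched comparisons. PSBY and PSB27 had log2 fold changes of 0.38 and 0.47 and did not pass (adjusted p = 0.0742 and 0.489). PSBY passed with median centring (0.89, adjusted p = 5.22e-04), on the deposited scale (1.45, 0.00146), with the pseudocount (0.43, 0.00142) without white array 5 (0.43, 0.0421), without white arrays 5 and 6 (0.47, 0.0126), without these numbers in both groups (0.49, 0.0145) and after removing the similarity at 6 numbers (0.50, 0.0423), but had an adjusted p of 0.414 with pairs averaged. Adjusted over the list alone, 1 of the 3 members changed, as over all probes. The list did not pass as a set (camera adjusted p = 0.135, and adjusted p = 0.215 with an estimated correlation).

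LHB1B2 was the 1 tested member of the light-harvesting list. Its normalised intensity was 18.1 ± 7.97 in white and 5.08 ± 0.811 in blue light (n = 6 each, adjusted p = 0.00163, and 0.0439 averaged), and on the deposited scale it had a log2 fold change of -0.95 (adjusted p = 0.199). PSAN, a lumenal subunit of photosystem I and the 1 tested member of its list, had a log2 fold change of -1.10 (adjusted p = 0.0220, and 0.153 averaged), which was -0.08 on the deposited scale. It did not pass with median centring (-0.63, adjusted p = 0.151), without white arrays 5 and 6 (-0.63, 0.0689), without blue array 4 (0.0505) or without number 2 (0.0514). In the added list of photosynthetic genes, 2 of 13 tested members were higher, 3 lower and 8 not past the threshold over 12 arrays, with the same counts adjusted over the list alone, and 1 was higher and 2 lower with pairs averaged. ATAB2, an activator of photosystem translation, fell by 1.56 on the log2 scale (9.54e-04 and 0.0283). AT1G22700, the photosystem I assembly protein PYG7, had a log2 fold change of 1.62 (0.0144 and 0.0927), but 1.37 without number 3, where it did not pass (0.0608), and 2.22 without white arrays 5 and 6. As a set the list had an adjusted p of 0.882, with a median log2 fold change of 0.04 and a mean of -0.05. LHB1B2, PSAN, PSB27, PYG7, PRXIIE, AT5G65360, PRK, CHLP and CHLM were chosen after their values were seen.

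**Figure D3:**
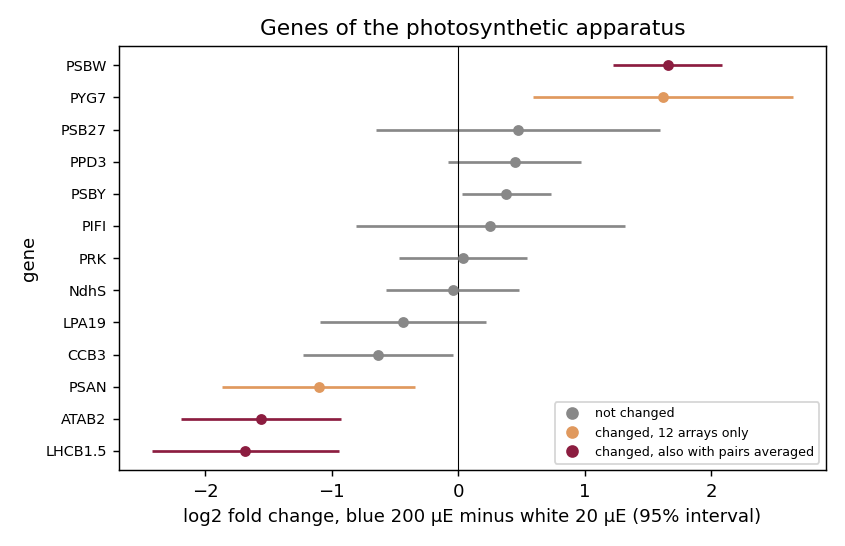
Log2 fold changes, blue over white, of 13 genes of the photosynthetic apparatus with their 95% intervals over 12 arrays. PSBW lies at 1.66, and LHCB1.5 (LHB1B2) and ATAB2 lie at -1.68 and -1.56; all 3 also passed with pairs averaged.

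Of 6 plastid ribosomal genes with a probe of 1 gene, 4 were tested. AT1G29070, above 0 on every white array and at 0 on every blue array, was among those left out. None of the 4 tested genes passed over 12 arrays. They had log2 fold changes from -0.31 to 1.34, with AT3G13120 at 1.34 and AT3G54210 at 0.41 (adjusted p = 0.0845 and 0.156), and 0 passed adjusted over the list alone. On the deposited scale both AT3G13120 (1.69) and AT3G54210 (1.13) passed (adjusted p = 0.00563 each). AT3G13120 also passed without white array 6 (1.82, 0.00782), without white arrays 5 and 6 (2.15, 0.00225) and with arrays 3 numbers apart averaged (0.00534), and AT3G54210 with median centring (0.58, 0.0455), but with adjacent pairs averaged the adjusted p was 0.190 and 0.453. The set had an adjusted p of 0.341, and an adjusted p of 0.389 with an estimated correlation. PRK of the Calvin cycle list had a log2 fold change of 0.04 (adjusted p = 0.919), and CHLP (AT1G74470) and CHLM of chlorophyll synthesis had -0.34 and -0.35 (0.213 and 0.242). On the deposited scale PRK and CHLP passed at 0.88 and 0.77 (adjusted p = 0.0128 and 0.0207), the latter in the other direction, and CHLM was at 0.26. CHLM passed without white array 5 (-0.52, adjusted p = 0.0411) and without white arrays 5 and 6 (-0.63, 0.00813), and CHLP after removing the similarity at 6 numbers (-0.51, 0.0455). PRXIIE (AT3G52960), a plastid peroxiredoxin and the 1 tested member of the fixed antioxidant list, had a log2 fold change of -1.53 (0.00396, and 0.0504 averaged, or 0.0298 averaged with a block). No tested probe named 1 gene in 14 of the 21 lists, among them the photoreceptors, the cytosolic housekeeping genes and the markers of root, seed and flower.

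Several added lists held genes that changed in opposite directions. Calls in both directions are not particular to these lists. Of all tested probes, 45.1% were called over 12 arrays (551 higher, 729 lower) and 19.75% with pairs averaged. In the redox list, 1 of 6 tested genes was higher and 3 were lower over 12 arrays, and 1 and 1 with pairs averaged. NTRC rose from 0.225 ± 0.126 to 0.784 ± 0.192 (adjusted p = 2.78e-04, and 0.0160 averaged), and GLDH went from 0.317 ± 0.174 to 0.0603 ± 0.0257 (9.75e-04 and 0.0286). Of 15 tested pentatricopeptide repeat proteins, which act on organelle RNA, 6 were higher and 4 lower, and 2 and 2 with pairs averaged. AT4G04370 rose 3.67-fold (9.94e-05 and 0.0169) and AT2G46050 3.41-fold (0.00110 and 0.0375). Of 6 mTERF genes, 4 were lower and 0 higher over 12 arrays, and 2 and 0 with pairs averaged. AT1G62010 fell by 1.85 on the log2 scale (3.17e-04 and 0.0255).

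Among 6 plastoglobule genes, 2 were higher and 4 lower over 12 arrays, and 1 and 1 with pairs averaged. AT3G24190, a kinase of the ABC1 family, fell by 1.60 (1.68e-04 and 0.0166), and AT5G09820, a fibrillin, had a log2 fold change of 1.14 (0.00200 and 0.0533). Among 7 histone H3 and kinesin genes, 3 were higher and 1 lower, or 3 and 2 adjusted over the list alone and 2 and 1 with pairs averaged. AT1G13370 rose 3.05-fold (8.89e-04 and 0.0382) and AT1G09200 fell by 1.21 (0.00190 and 0.0499). AT5G65360 had a log2 fold change of 1.13 (0.0440 and 0.198), and 0.46 without white arrays 5 and 6. Its call ended in 8 of 12 refits without 1 array. AT1G09200 and AT5G65360 are both listed as histone H3.1 genes. Whether their probes tell these copies apart was not tested. On the deposited scale AT1G62010, AT3G24190 and AT1G09200 did not pass (adjusted p = 0.0596, 0.106 and 0.0927), and AT3G24190 did not with the pseudocount (0.557). None of the 6 added lists passed as a set with camera. The adjusted p was 0.200 for the pentatricopeptide repeat list, 0.382 for mTERF and 0.882 for the redox, plastoglobule and histone lists, and with an estimated correlation the adjusted p was 0.298, 0.795 and 0.879. Camera used only genes without a 0. For the plastoglobule list these were 4 genes, without AT1G51110 (-5.02) and AT3G24190 (-1.60), which both fell. The camera direction of these 4 genes was up, with a median of 0.10 and a mean of -0.10. It was also up for the histone list, whose median was -0.28 and mean 0.19.

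**Figure D4:**
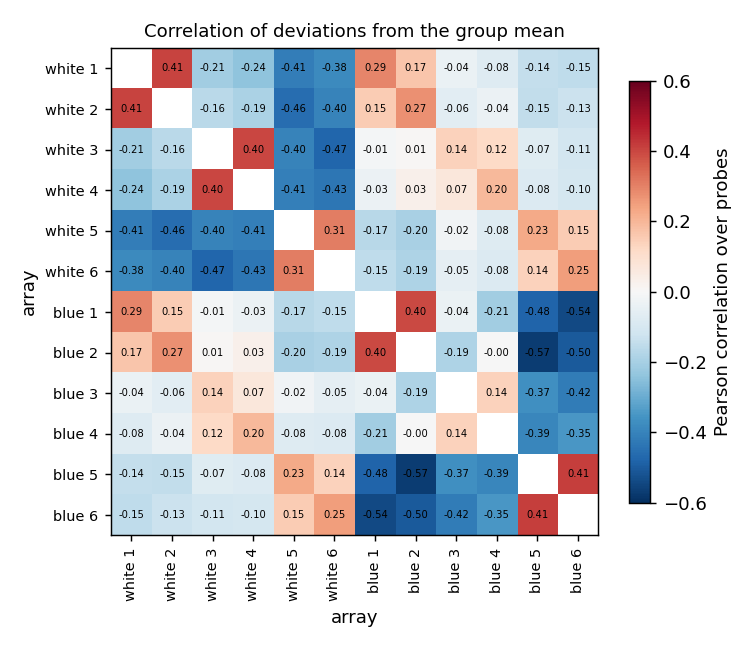
Pearson correlations over probes between the deviations of the 12 arrays from their group means, by group and number, with the arrays on both axes. Adjacent arrays of a group correlate at 0.14 to 0.41, and arrays of the same number at 0.14 to 0.29 between the groups.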

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

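The test of repeat measurements by mutual best partners alone, and that of gene copies sharing a spot, were chosen only after the result was seen. The rule set beforehand also asked for correlations over 0.3, which blue arrays 3 and 4 missed (0.141). In 8 of 80 groups of array values tested, 1 array stood apart from the others by Dixon's criterion, and chance alone would pick about 1 in 20. All values are normalised log2 intensities. AT3G60590 stood at -9.60 on white array 5 and PSBW at 3.40 on the same array, against 3.88 to 4.01 on the others for PSBW. On white array 6, AT1G10310 stood at 0.81 and NTRC at -1.06. AT1G79220 stood at -8.78 on blue array 3 and AT4G18540 at -8.66 on blue array 2. PSBY stood at 0.58 on blue array 6 and AT1G22700 at -2.43 on blue array 1.

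The count of 1280 changed probes was the largest among 100 splits of the 12 arrays. It was reached by 1 split, the real one, with a highest other count of 1. Among the 32 splits that part every same-numbered pair, 1 reached it, again the real one, and the highest other count was 1. Chance can be excluded only as far as the 12 arrays are separate samples. Other splits mix blue and white arrays, so a difference between the groups widens their spread and holds their counts low. The highest other count is thus not the number of calls expected by chance. On simulated values without any change, the fit on 12 arrays made 28 calls when adjacent arrays shared their deviations. With pairs averaged the real count was 527 and the highest other count 0, but 10 splits, 1 of which is the real one, are too few for a share under 0.05. Repeat measurements of 3 samples per group may explain part of the size of the count, since 6 of 6 adjacent pairs were mutual best partners. Whether light colour or strength lies behind the calls was not tested.

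LHB1B2 and PSAN were lower under blue light while PSBW was higher. A scale that differs between the groups for bright spots stays open, since the share of higher calls in the brightest 10% of probes (51.0% of 155) is largely set by the normalisation, and on the deposited scale LHB1B2 was at -0.95 and PSAN at -0.08. Copies of the LHCB1 genes could share the LHB1B2 spot, and 0 other LHCB1 genes had a probe with 1 gene, so this cannot be told apart from a change of LHB1B2 itself. The log2 fold change of PSBW exceeded that of LHB1B2 by 3.34 ± 0.92 (SD over 3 averaged pairs). It did so in 6 of 6 number-matched comparisons. This follows from PSBW being higher and LHB1B2 lower in each of them, so it adds no support. A response to the light regime stays open, as untested.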

How the results depend on the processing

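Alternatives that left out white arrays 5 and 6, left out these numbers in both groups, averaged pairs with a block removed the similarity of probes 6 numbers apart or joined the pseudocount to an estimated correlation, and all those of the added lists, were chosen only after the data were seen. The count of 1280 changed probes (551 higher, 729 lower) fell to 741 (364 and 377) without the dimmest 50% of probes, which tests fewer probes. It was 527 (226 and 301) with adjacent arrays averaged and 664 (277 and 387) when these averages also had a block, where fewer samples enter. On the deposited scale 869 were higher and 331 lower. Without 1 array or number the counts ran from 1031 to 1304, with 438 to 565 higher and 586 to 739 lower. The other alternatives kept the count within 1.5 times, among them 1413 without white arrays 5 and 6 and 1322 after removing the similarity at 6 numbers. With the replicate number as a block, 1382 probes changed, 1223 of them shared with the fit without it. The block ended the calls of 2 named genes, AT4G31210 (adjusted p = 0.114) and AT1G51110 (0.0693), and changed no other call among 39.

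The photosystem II list had a median log2 fold change of 0.37 to 0.73 without 1 array or number, and up to 1.45 over all alternatives (deposited scale). It passed with the pseudocount (0.50, adjusted p = 0.0328), but not when the correlation was also estimated (0.0715). The plastid ribosomal list ranged from 0.33 to 0.48 without 1 array or number and from 0.13 (similarity at 6 numbers removed) to 1.04 (deposited scale) over all alternatives. Of genes not past the threshold, PSB27 turned to -0.00204 without white arrays 5 and 6, CHLM to 0.26 and AT1G74470 to 0.77 on the deposited scale, and AT1G74470 to 0.21 with median centring. PRK ran from -0.0892 to 0.20 without 1 array or number. The direction of the camera test, not always the sign of the median given here, turned for the histone list without white arrays 5 and 6 (-0.25, against -0.28). It turned for the plastoglobule list (0.10) on the deposited scale (0.49), with the pseudocount (-0.91), with arrays averaged either way or with a block (-0.95), without white replicate 3 (-1.06) and without replicate 3 (-1.05), and that list ran from -1.06 to 0.17 without 1 array or number. AT3G24190 (log2 fold change -1.60) had a 0 on 1 white array, so camera left it out of the main test. It entered with arrays averaged and with the pseudocount, so those turns reflect in part which genes entered. The medians without white replicate 3 (-1.06) and without replicate 3 (-1.05) lay near that with arrays averaged (-0.95), so AT3G24190 may have entered there too. The cause of the turns on the deposited scale and of the histone list was not tested. No other named gene turned. With pairs averaged 28 of 36 named genes kept their side of the threshold and 8 no longer passed. On the deposited scale 27 of 39 kept their side and direction, 6 no longer passed and 4 passed anew. The direction of 2 turned, and of these AT1G74470 also passed there (limma adjusted p = 0.0207). The zeros, which leave 599 probes untested, limit what dim probes can show.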

Other observations

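The tests of fold changes 6 probe numbers apart against chance and against a smooth drift, and of dim spots lost on white arrays 5 and 6, were chosen only after the result was seen. Some probes were listed at 0 on every array of 1 group and above 0 on every array of the other. There were 14 listed at 0 in blue light, with 4 named genes. DRT101 had a median intensity of 0.241 in white light, AT5G05330 0.429, AT1G72890 0.107 and AT1G29070, a plastid ribosomal protein, 0.0607. There were 3 listed at 0 in white light, with 2 named genes, AT2G21530 at a median of 1.98 in blue light and AT2G27680 at 0.505. These 2 genes have consecutive probe numbers, 3556 and 3555. Without white values they could not enter the tests of fold changes by probe number below, so a place effect on them stays open. All genes named here at 0 in 1 group were chosen after their values were seen.

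Runs of probe numbers that rose together were seen first and then tested. Signal that depends on the place of a spot, if near numbers were near spots, is argued against for the fold changes over all 12 arrays, whose correlation between probes with numbers differing by 1 was -0.0168. Within arrays 5 and 6 alone it was 0.103, over the bound of 0.1, against -0.00227 for arrays 1 and 2 and 0.0278 for arrays 3 and 4, so a place effect in that pair stays open. A look over 21 distances (each from 1 to 16 and 5 larger ones) then showed a correlation of 0.12 at a distance of 6, and in 0 of 1000 shuffles did the largest of the 21 correlations reach it. Distances of 12, 24, 48 and 96 stood at 0.0586, 0.0865, 0.0795 and 0.0857 and the 2 largest, also multiples of 6, at 0.0373 and -0.0210, but 16, which is no multiple of 6, also stood at 0.0690. A smooth drift along the numbers is argued against for the fold changes over all 12 arrays, since the largest correlation at distances of 1 to 5 and 7 was -0.0122. For arrays 5 and 6 alone these distances stood at 0.0775 to 0.116 against 0.129 at 6, so a drift in that pair stays open. Deviations of single arrays from their group means correlated at a distance of 6 with a median of 0.238, which met the bound set beforehand. They also did so at a distance of 1 (0.275), 5 (0.214) and 7 (0.206), so they are not particular to 6. The median was lower at larger distances (0.0939 at 16, 0.0449 at 48 and 0.011 at 96), the shape of a drift along the numbers within single arrays. A place that recurs every 6 numbers therefore cannot be told apart from an order of the probes that recurs, which was not tested. A candidate explanation is uneven signal across the array, and no biological explanation was tested; probes are not independent replicates.

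On white arrays 5 and 6, 1 probe stood at the maximum of 100 and the next brightest at 37.2 and 40.6, against 72.8 to 100 for the second brightest probe on white arrays 1 to 4. The first probe also stood at 100 on white arrays 3 and 4, so its true level there is not known. The next 50 brightest probes stood at a median of 0.618 times their median-scaled level on white arrays 1 to 4. The larger number of zeros on these arrays was 498, within the 404 to 574 of white arrays 1 to 4.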
